A study of Mus musculus with 10 samples.

How the data were processed

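RNA was measured by bulk sequencing in the left atrium of wild-type mice 2 weeks after transverse aortic constriction (TAC), which narrows the aortic arch and raises the pressure the heart pumps against, or after sham surgery. Surgery was done at 2 months of age, in male mice of the C57BL/6J strain per the series' design text. There were 5 sham and 5 TAC libraries, grouped by their titles. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples, part of which may be technical. The sources describe the material and the library kit in 2 ways. The design text names the left appendage, an RNeasy kit and a TruSeq RNA kit, whereas the sample labels name the left atrium, an RNeasy Plus kit and the Nugen Trio low-input RNA kit. Which of them was used is not known here, and neither source gives a sequencing batch.

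The deposited values are raw counts of reads or read pairs per gene symbol, 1 table per library, which the authors made without normalization. STAR for alignment, bcl2fastq for demultiplexing and the mouse build mm10 appear without versions in the submitters' processing notes. The counter, its strand setting and the gene annotation are not given in the sources used here. Each table closes with 5 tallies that name no gene, and these stayed out of library sizes and tests. Their mean shares of all reads in sham and TAC were 3.12% and 3.76% for reads in no gene, 4.31% and 5.79% for reads ambiguous between genes, and 15.8% and 13.4% for reads aligned to several places. Of the 48397 gene symbols, 46294 (95.7%) matched a single gene of the GENCODE M21 annotation of GRCm38, the assembly also called mm10, which gave the coordinates and overlaps printed here. Because the strand setting is not stated, reads of a gene and of an antisense neighbour cannot be told apart, and copies with near-identical sequence, such as Hspa1a and Hspa1b or the globin genes, can split their reads.

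Total counts over genes ran from 17117306 to 43956384 per library. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr at its default settings, robust estimation and group as the only term, which left 15175 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change (TAC over sham) was its size divided by the square root of F. Levels are TMM-normalised CPM (counts relative to effective library size), as mean ± SD over 5 libraries. Before the data were examined, 45 gene lists (24 of pathways and 21 of cell type markers) were written from general knowledge. Of these, 42 had at least 3 tested members and were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 42 lists, with camera at an estimated correlation and fry beside it. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. Single measures per library were compared with exact two-sided permutation tests over all 252 regroupings, for which the smallest possible p is 0.00794. Principal components were taken from log2 CPM with a prior count of 2.

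The rule for genes named in the text was fixed at the same time. It took preset genes, among them Etv1, Gja5, Nkx2-5, Nppa, Nppb and Myh7. It then took the 10 largest increases and the 10 largest decreases among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' CPM, passing over predicted genes and pseudogenes. From each list it took up to 2 called members with the smallest adjusted p, or 4 in the lists of rapid conduction, hypertrophy and fibrosis genes, plus 1 of the rarer direction, and the most abundant member where none was called. The text does not print every gene the rule took. Alternatives fixed in advance were DESeq2 size factors, library size or upper-quartile factors for scaling, other filters on low counts, DESeq2 1.42.0, limma voom with quality weights, non-robust estimation, the replicate number as a block, removal of mitochondrial, haemoglobin and non-polyadenylated genes, stricter thresholds, and each of the 10 libraries left out. Leaving out the 2 shallow sham libraries, thinning all libraries to the shallowest, and offsets for gene length and GC content (14674 genes, 96.7% of those tested) were added after the data were seen. The tests were checked on simulated data for this comparison. Of the simulated genes, 14491 were tested. A fold change was set for 200 genes drawn at random, and the intercalated disc list was lowered as a set. Of the 200, 32.8% of the 1.5-fold, 68.7% of the 2-fold and 95.5% of the 4-fold changes were recovered. Of the 158 calls in all, 7% were false. Far fewer genes were changed than were called in the real data, and genes were drawn independently, so changes of that breadth were not checked. No library was left out of the comparison. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.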

Results

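Left atrial RNA was compared between 5 libraries from mice with a constricted aorta (TAC) and 5 libraries from sham-operated mice, 2 weeks after surgery. Throughout, n counts libraries. The title of the series names the transcription factor ETV1 and genes of rapid conduction, so the comparison asks how these, and the atrial transcriptome at large, differed after pressure overload. Total counts over genes were 17117306, 17154462, 37924950, 43956384 and 32843150 in sham replicates 1 to 5. They were 41358617, 35174756, 29493200, 29656877 and 31950166 in TAC replicates 1 to 5. Depth did not differ between groups by more than its spread (exact permutation p = 0.50).

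The atria of the 2 groups had widely different transcriptomes. By a list test with a preset correlation, matrix and cell-cycle genes were higher after TAC, whereas genes of mitochondrial metabolism, of the atrial contractile and calcium-cycling apparatus, and of the immediate early response were lower. None of these list calls held with an estimated correlation (adjusted p from 0.14 to 0.44), and calcium handling genes moved in both directions. The neurohormonal list lost its call as well (camera adjusted p from 0.0044 to 0.14), though its estimated correlation of 0.0033 lay below the preset 0.01. A higher correlation among a list's own members was therefore not the reason for every loss. Of 15175 genes tested with edgeR, 4383 were higher and 4233 lower in TAC, and 1781 and 1229 of these differed by a log2 fold change of at least 1. The groups' CPM did not overlap for 41.7% of tested genes, against 0.794% expected by chance. The first principal component held 70.2% of the variance and separated the groups. Mitochondrially encoded genes took 16.3% ± 1.42 of counts in sham and 10.99% ± 2.097 in TAC (SD, n = 5, exact permutation p = 0.0079). The 20 most abundant genes took 29.2% ± 1.37 and 21.2% ± 2.02 (exact permutation p = 0.0079). These shares affect the scaling. With library size as the only scaling the median log2 fold change of all tested genes moved from 0.01 to 0.37, and 7741 genes were higher and 1929 lower, so that 80.1% of calls were increases instead of 50.9%. Of the genes called under both scalings 30 had opposite signs. Changes are given relative to TMM scaling. Where counts of risen and fallen members of a list are given without a second pair, the counts adjusted over the list alone were the same.

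**Figure D1:**
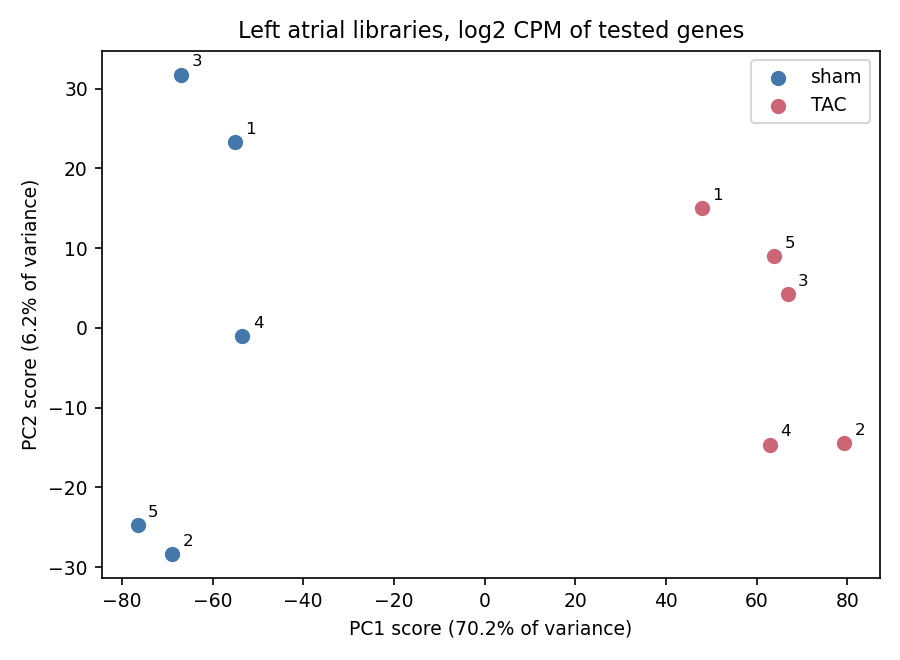
Scores of the 10 libraries on the first 2 principal components of log2 CPM over the tested genes, with sham in blue, TAC in red and replicate numbers beside the points. The horizontal axis (70.2% of variance) separates the groups, and the vertical axis holds 6.2%.

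Etv1, at chromosome 12, 38779380 to 38870484 (GRCm38), fell from 21.7 ± 3.74 CPM in sham to 13.6 ± 1.82 in TAC (SD, n = 5), a log2 fold change of -0.68 (SE 0.13, adjusted p = 0.0010). All 5 TAC libraries lay below the 5 sham libraries (exact two-sided permutation p = 0.0079, the smallest possible). Gja5, which encodes the gap junction protein connexin 40 and lies at chromosome 3, 96904693 to 97077416, fell from 159 ± 30.7 to 79.0 ± 22.0 CPM (log2 fold change -1.01, SE 0.20, adjusted p = 0.0012). Nkx2-5, a cardiac homeobox factor, was at 80.6 ± 8.99 and 84.5 ± 5.08 CPM (adjusted p = 0.52). Among the 17 tested members of the rapid conduction list, 5 rose and 8 fell, or 5 and 9 adjusted over the list alone. The sodium channel genes Scn10a (log2 fold change -2.43, SE 0.36) and Scn4b (-3.65, SE 0.48) and the T-box factor Tbx5 (-0.81, SE 0.08) fell, while the calcium channel subunit gene Cacna2d2 (0.77, SE 0.17) rose. The list as a whole did not pass the test against other genes (median log2 fold change -0.54, camera adjusted p = 0.21, adjusted p = 0.54 with an estimated correlation). Its members moved down on balance (fry adjusted p = 0.0080), but with library size as the only scaling 6 rose and 7 fell, with a median of -0.18. With library size as the only scaling Etv1 no longer passed the threshold (log2 fold change -0.33, adjusted p = 0.058, within a range of 1.2e-05 to 0.058 over its 23 alternatives). Under the same scaling Nkx2-5 rose by 0.42 on the log2 scale (adjusted p = 0.0026, within a range of 0.0026 to 0.93 over its alternatives).

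**Figure D2:**
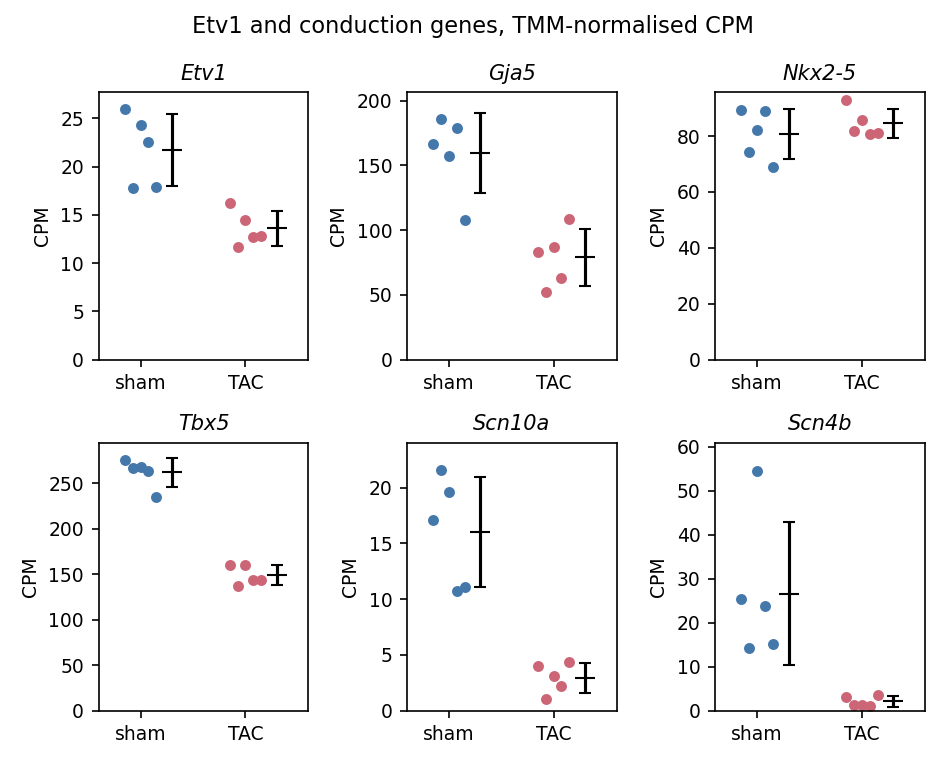
TMM-normalised CPM of Etv1 and 5 conduction genes in each library (points), with mean ± SD beside them (n = 5 per group). Etv1 lay at 13.6 ± 1.82 CPM in TAC against 21.7 ± 3.74 in sham, and Nkx2-5 overlapped between groups.

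The list of slow (nodal) conduction genes had 5 members that rose and 4 that fell (5 and 5 adjusted over the list alone) and was not called (camera adjusted p = 0.79). Its median was positive (0.06), while its mean (-0.23) and test pointed down. Scaled by library size alone, 5 rose and 2 fell, with a median of 0.43. Gjc1, a connexin gene, rose by 1.14 (SE 0.11), and the T-type calcium channel gene Cacna1h fell by 1.48 (SE 0.19) on the log2 scale. Potassium channel genes were lower. In that list 17 of 21 fell and 1 rose (median -1.04, camera adjusted p = 1.2e-07, adjusted p = 0.14 with an estimated correlation). Kcnd2 and Kcnd3, which encode channels of the transient outward current, fell from 53.1 ± 4.81 to 14.8 ± 2.69 and from 31.8 ± 2.78 to 7.14 ± 1.87 CPM, while the regulatory subunit gene Kcne4 rose from 1.54 ± 0.379 to 13.2 ± 3.88 CPM (SD, n = 5). Intercalated disc genes were lower as well, with 13 of 16 down and 1 up (median -0.69, camera adjusted p = 1.0e-05, adjusted p = 0.042 with an estimated correlation). This was the single fixed list whose call held with an estimated correlation. Dsg2, a desmosomal cadherin gene, fell by 1.45 (SE 0.12), Tmem65 fell by 1.27 (SE 0.11) and Des, which encodes desmin, rose by 0.93 (SE 0.23). Genes near atrial fibrillation loci did not pass as a list (2 up and 8 down, 2 and 9 adjusted over the list alone, camera adjusted p = 0.13). They moved down on balance (fry adjusted p = 2.6e-05, within a range of 2.6e-05 to 0.27 over the alternatives), but 4 rose and 4 fell with library size as the only scaling. With library size as the only scaling 8 intercalated disc members fell and 2 rose. The log2 fold changes of Jup and Vcl, chosen after their values were seen, changed sign.

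In the list of neuregulin, ERBB receptor and ERK feedback genes, 9 of 17 members rose and 2 fell (median 0.37, camera adjusted p = 0.027, adjusted p = 0.25 with an estimated correlation). The ligand gene Nrg1, at chromosome 8, 31814551 to 32884029, rose from 2.64 ± 1.21 to 73.4 ± 22.2 CPM (log2 fold change 4.83, SE 0.33, adjusted p = 1.7e-06), while the receptor genes Erbb4 and Erbb3 fell by 1.42 (SE 0.12) and 0.95 (SE 0.12) on the log2 scale. Neurohormonal genes were lower, with 10 of 19 down and 3 up, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.0044, adjusted p = 0.14 with an estimated correlation). Npr2, chosen after its values were seen, changed sign with library size as the only scaling. The mineralocorticoid receptor gene Nr3c2 fell by 2.19 (SE 0.14) and Corin, the protease that processes natriuretic peptide precursors, by 1.83 (SE 0.13), whereas Edn1, which encodes endothelin 1, rose from 3.92 ± 1.26 to 50.7 ± 13.0 CPM (SD, n = 5).

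Hypertrophy and fetal genes moved in both directions, with 11 up and 5 down of 20, and the list was not called (camera adjusted p = 0.11). It passed upward with no filter on low counts (adjusted p = 0.024), with length and GC offsets (adjusted p = 0.0497) and with fry (adjusted p = 0.0054), within a range of 0.0054 to 0.46 over the alternatives. Nppa, which encodes atrial natriuretic peptide, rose from 5663 ± 433 to 9834 ± 491 CPM (log2 fold change 0.80, SE 0.11, adjusted p = 8.6e-05). Its exonic bases are shared with Gm13054 to 61.5%. Nppb rose from 1077 ± 310 to 1550 ± 150 CPM (log2 fold change 0.52, SE 0.18, adjusted p = 0.025). That call was lost without sham replicate 5 (adjusted p = 0.058) or TAC replicate 5 (adjusted p = 0.052), within a range of 0.0011 to 0.058 over its alternatives. Myh7, the slow myosin heavy chain gene, fell from 569 ± 193 to 253 ± 53.8 CPM (log2 fold change -1.17, SE 0.24, adjusted p = 0.0015). Actn1 rose by a log2 fold change of 2.04 (SE 0.19), Mybpc2 by 1.99 (SE 0.24) and Ankrd2 by 4.12 (SE 0.51), and Flnc, which encodes filamin C, fell by 2.33 (SE 0.33). Sarcomere genes were lower, with 15 of 20 down and 1 up (median -0.78, camera adjusted p = 5.6e-07, adjusted p = 0.24 with an estimated correlation). Tcap fell from 2508 ± 148 to 499 ± 111 CPM and Ldb3 from 1542 ± 86.3 to 716 ± 53.9, while Mybpc3 rose from 1613 ± 280 to 2532 ± 270 CPM (SD, n = 5). Of 15 atrial identity genes 11 fell and 0 rose (camera adjusted p = 8.3e-06, adjusted p = 0.14 with an estimated correlation), including Stard10 (log2 fold change -2.40, SE 0.13) and the kinase gene Sbk2 (-2.07, SE 0.15). Scaled by library size alone, 7 of them fell and 3 rose. Of 22 calcium handling genes 12 fell and 3 rose (camera adjusted p = 0.00049, adjusted p = 0.14 with an estimated correlation). Atp2a2, the sarcoplasmic reticulum calcium pump gene, fell from 20974 ± 1671 to 5312 ± 1083 CPM, and Pln, its inhibitor phospholamban, from 2781 ± 536 to 515 ± 138 CPM. The exonic bases of Pln are shared with Cep85l and Gm47644 to 64.7%. Scaled by library size alone, 10 calcium handling members fell and 7 rose. The log2 fold change of Asph, chosen after its values were seen, changed sign.

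**Figure D3:**
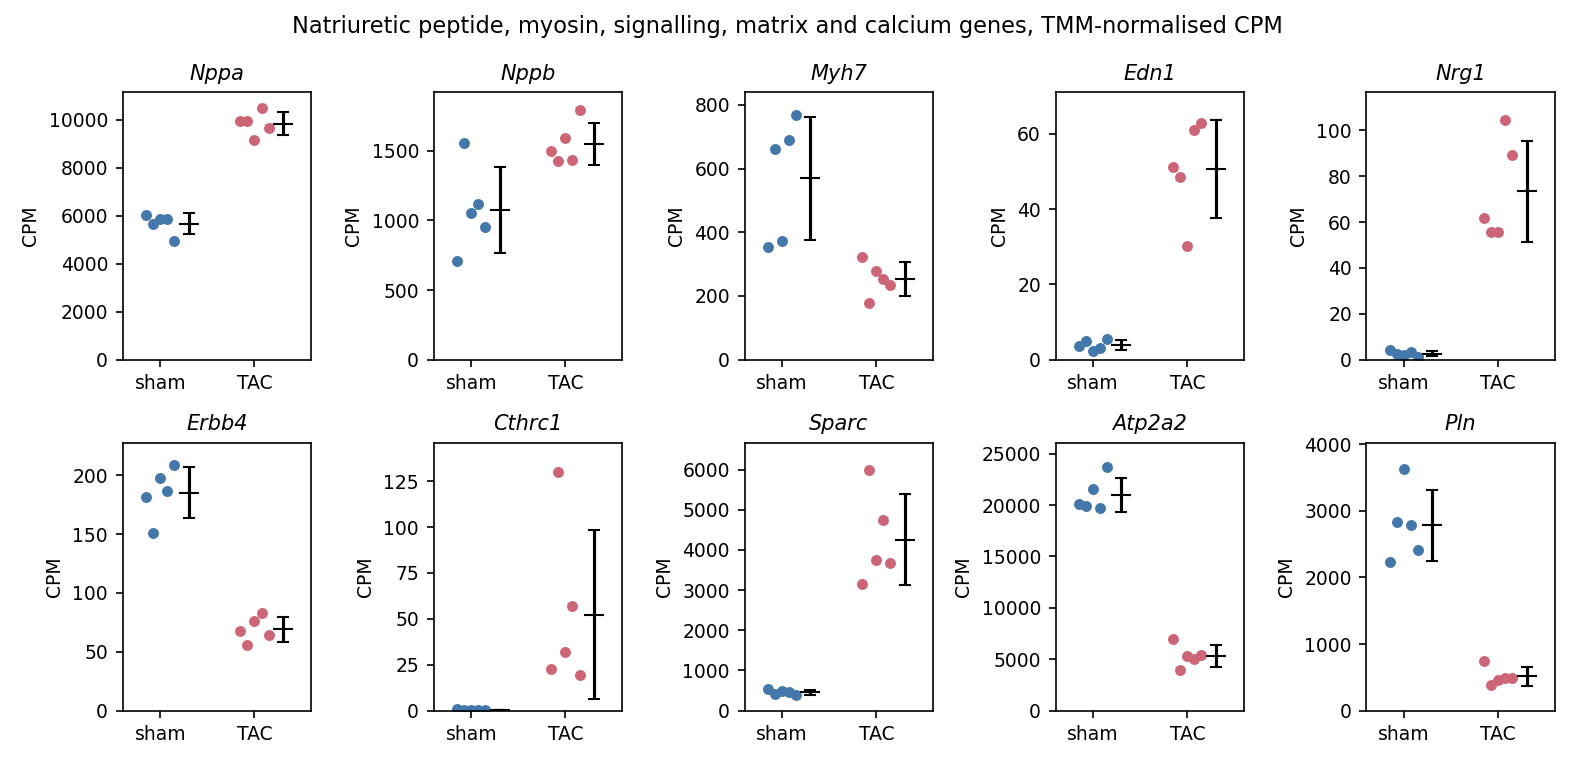
TMM-normalised CPM of natriuretic peptide, myosin, signalling, matrix and calcium-cycling genes in each library (points), with mean ± SD (n = 5 per group). Nrg1 rose from 2.64 ± 1.21 to 73.4 ± 22.2 CPM and Atp2a2 fell from 20974 ± 1671 to 5312 ± 1083.

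Fibrosis matrix genes were higher. Of these, 34 of 37 rose and 0 fell (median log2 fold change 2.68, camera adjusted p = 3.9e-22, adjusted p = 0.23 with an estimated correlation). The collagen-binding glycoprotein gene Sparc rose from 455 ± 62.6 to 4257 ± 1126 CPM, Col8a1 from 23.9 ± 4.48 to 451 ± 203, Cilp from 3.49 ± 1.61 to 116 ± 31.0 and Wisp2 from 8.98 ± 2.99 to 288 ± 109 (SD, n = 5). Matrix proteases and their inhibitors rose in 12 cases and fell in 4 of 17 (camera adjusted p = 0.00016, adjusted p = 0.23 with an estimated correlation), with the inhibitor gene Timp1 up by 3.42 (SE 0.14), Adamts2 up by 2.80 (SE 0.21) and Mmp9 at a log2 fold change of -2.74 (SE 0.38). All 27 cell-cycle genes rose (median log2 fold change 4.69, camera adjusted p = 9.7e-22, adjusted p = 0.19 with an estimated correlation), among them Tyms (2.37, SE 0.14) and the replication helicase gene Mcm5 (2.64, SE 0.19). The 10 largest increases by the rule for named genes were Col11a1, Serpinb1c, Cthrc1, Cemip, Tnnt3, Depdc1a, Hmmr, Xkr5, Ccnb1 and Ube2c, with log2 fold changes from 8.55 (SE 1.20) for Col11a1 to 6.19 (SE 0.66) for Ube2c. Their sham counts over 5 libraries ranged from 4 for Serpinb1c, 6 for Depdc1a, 11 for Xkr5, 12 for Col11a1 and 15 for Cemip to 174 for Tnnt3, and the fold changes of genes with few counts are imprecise. Without TAC replicate 2 the log2 fold change was 7.46 for Col11a1 and 6.45 for Cthrc1. It was 8.02 for Cemip without sham replicate 5 and 7.45 for Depdc1a without sham replicate 4. Cthrc1, a collagen-associated secreted protein gene, rose from 0.409 ± 0.200 to 52.3 ± 45.9 CPM, and Tnnt3, the fast skeletal troponin T gene, from 1.29 ± 0.611 to 142 ± 79.7 CPM (SD, n = 5).

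Energy metabolism genes fell together relative to the RNA of these bulk libraries. Whether they fell within cardiomyocytes was not tested. Of 76 nuclear genes of oxidative phosphorylation 72 fell and 0 rose, or 75 and 0 adjusted over the list alone (median -0.82, camera adjusted p = 2.2e-13, adjusted p = 0.44 with an estimated correlation). All 17 tricarboxylic acid cycle genes fell (median -0.95, camera adjusted p = 4.2e-07, adjusted p = 0.39 with an estimated correlation), as did all 17 genes of branched-chain amino acid catabolism (median -1.01, camera adjusted p = 1.1e-11, adjusted p = 0.24 with an estimated correlation). Of 33 fatty acid oxidation genes 30 fell and 0 rose (median -1.02, camera adjusted p = 4.2e-09, adjusted p = 0.33 with an estimated correlation). Examples were the respiratory complex genes Sdha (1369 ± 128 to 531 ± 123 CPM) and Ndufs1 (670 ± 75.8 to 270 ± 59.3 CPM), Idh3a (880 ± 105 to 391 ± 101 CPM), Ivd (363 ± 25.7 to 119 ± 15.9 CPM) and Acsl1 (742 ± 136 to 206 ± 56.7 CPM). These medians stayed below 0 with library size as the only scaling (-0.47, -0.59, -0.65 and -0.66 in the order above), although Esrrg, a regulator chosen after its values were seen, changed sign. Glycolysis genes split into 7 up and 9 down of 22, or 7 and 10 adjusted over the list alone (camera adjusted p = 0.28). The muscle phosphofructokinase gene Pfkm fell by 1.40 (SE 0.11) on the log2 scale, and its platelet counterpart Pfkp rose by 1.40 (SE 0.14). The glucose transporter gene Slc2a4 fell from 443 ± 23.9 to 157 ± 29.6 CPM (SD, n = 5). Scaled by library size alone, the glycolysis median changed from -0.23 to 0.13, and Gpi1, Pkm and Pdk1, chosen after their values were seen, changed sign.

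**Figure D4:**
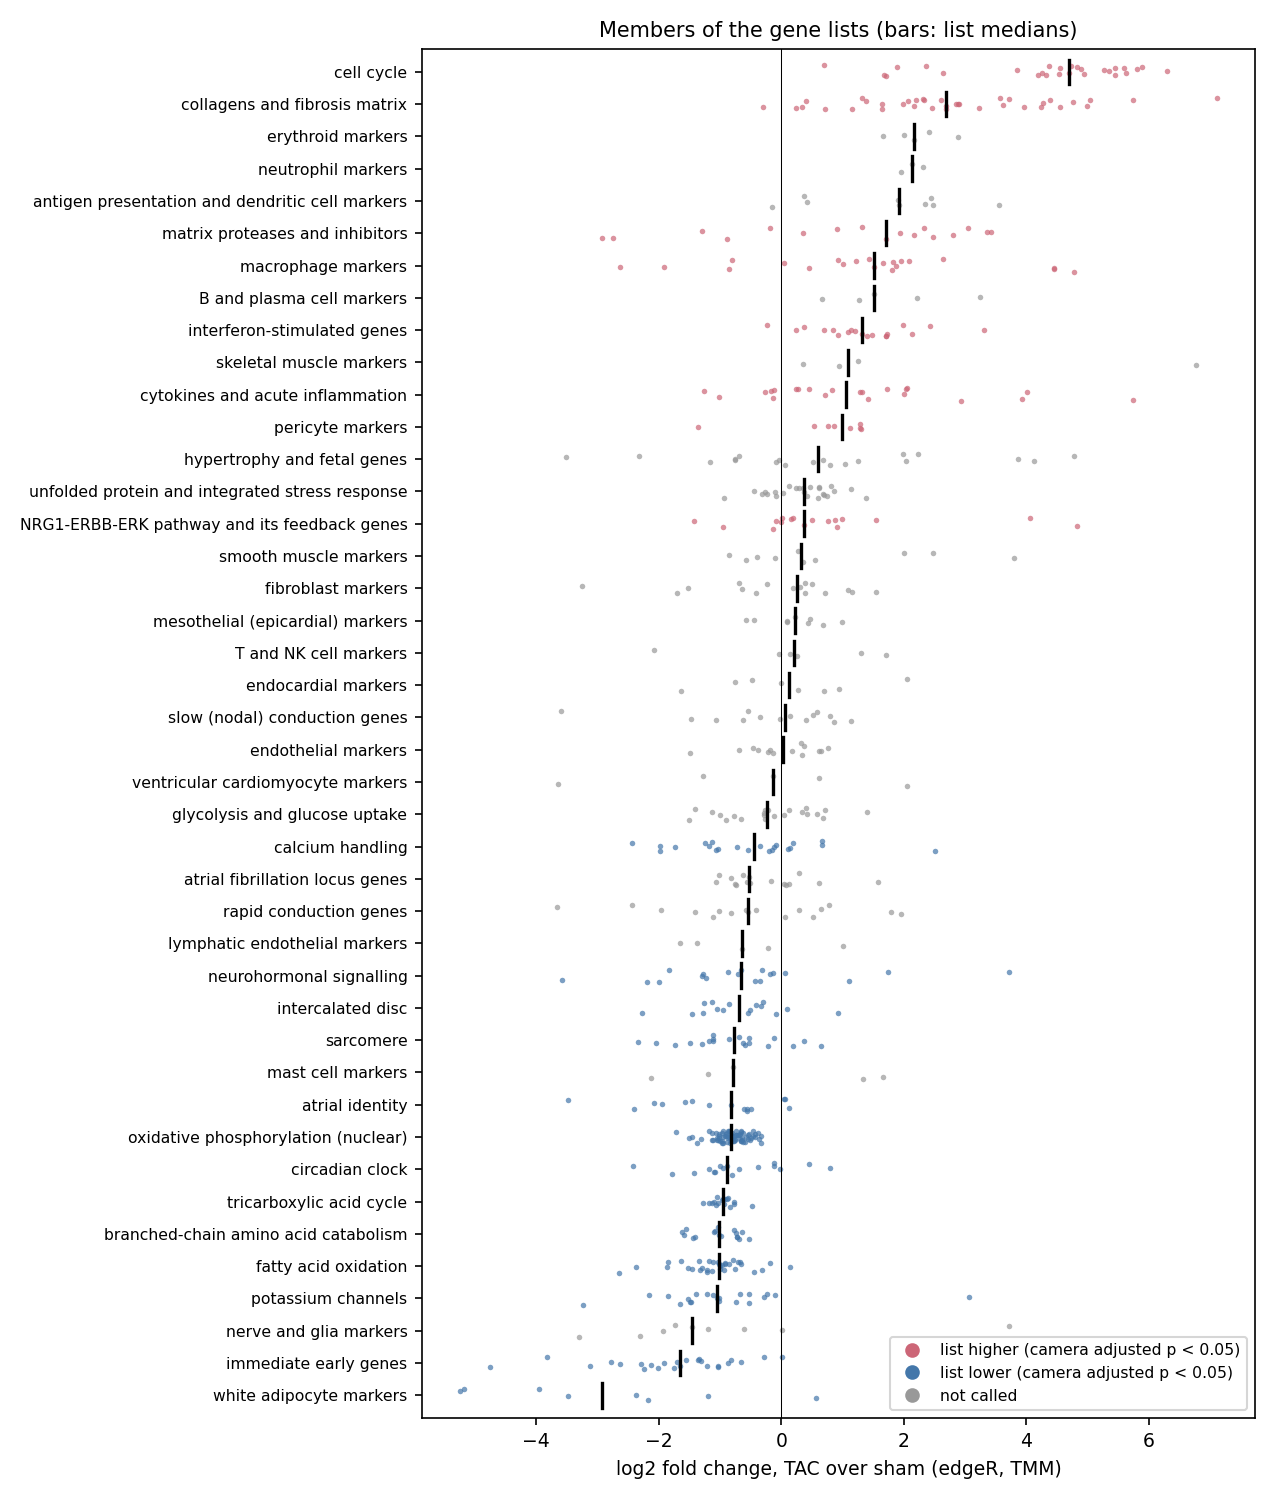
Log2 fold change (TAC over sham, horizontal axis) of each tested member (points) of the 42 tested lists, sorted by median (black bars). Red lists were higher and blue lists lower at a camera adjusted p under 0.05. With library size as the only scaling the median of all tested genes moved to 0.37, and the medians of the glycolysis and ventricular marker lists changed from negative to positive.

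Immediate early genes, which are induced within minutes of a stimulus, were lower in TAC. Of these, 22 of 25 fell and 0 rose, or 23 and 0 adjusted over the list alone (median -1.65, camera adjusted p = 1.6e-08, adjusted p = 0.27 with an estimated correlation). Nr4a3 fell from 122 ± 38.4 to 8.65 ± 2.04 CPM and Nr4a1 from 213 ± 68.8 to 24.6 ± 3.75 CPM (SD, n = 5). Circadian clock genes fell in 10 cases and rose in 2 of 17 (camera adjusted p = 0.0022, adjusted p = 0.18 with an estimated correlation). Cry2 fell by 1.42 (SE 0.10), Nr1d1 fell by 1.18 (SE 0.12) and Clock rose by 0.46 (SE 0.08). The unfolded protein response list was not called (13 up and 4 down of 25, camera adjusted p = 0.13), with Manf up by 0.70 (SE 0.09) and Dnajb9 down at a log2 fold change of -0.93 (SE 0.08). That list passed upward with no filter on low counts (adjusted p = 0.027), with limma voom (adjusted p = 0.044) and with fry (adjusted p = 0.0042), within a range of 0.0042 to 0.58 over the alternatives. Under library size scaling 18 members rose and 1 fell, and Hspa5, Canx and Xbp1 changed sign, of which Hspa5 and Xbp1 were chosen after their values were seen. The 10 largest decreases were Sfrp5, Hspa1a, Inmt, Penk, Ccl11, Hspa1b, Cpne5, Pck1, Cilp2 and Lrtm1. Sfrp5, a secreted WNT antagonist gene, fell from 34.8 ± 14.7 to 0.173 ± 0.159 CPM (log2 fold change -7.68, SE 0.50, adjusted p = 1.4e-06), and Inmt, an amine methyltransferase gene, from 71.4 ± 8.39 to 0.596 ± 0.251 CPM (-6.90, SE 0.22, adjusted p = 2.0e-08). The inducible heat shock gene Hspa1a stood at 88.4 ± 123 CPM in sham and 0.430 ± 0.167 in TAC. Its sham libraries differed widely among themselves. Leaving out sham replicate 5 changed the log2 fold change of Hspa1a from -7.66 to -6.40 and that of Hspa1b from -6.11 to -4.78. Leaving out 1 TAC library gave -8.32 for Sfrp5 and -6.04 for Pck1 (replicate 4), -6.81 for Penk (replicate 5) and -6.28 for Cpne5 (replicate 1).

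Inflammatory genes were higher. Cytokine genes rose in 12 cases and fell in 1 of 22 (camera adjusted p = 0.025, adjusted p = 0.44 with an estimated correlation). Il6 rose from 0.112 ± 0.0575 to 1.61 ± 0.438 CPM, Il1b rose from 0.442 ± 0.220 to 7.08 ± 3.90, and Cxcl14 fell from 18.6 ± 3.97 to 7.76 ± 3.31 (SD, n = 5). The cytokine call was lost with library size as the only scaling (adjusted p = 0.21, within a range of 0.0012 to 0.44 over its alternatives). Of 19 interferon-stimulated genes 16 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 2.0e-05, adjusted p = 0.27 with an estimated correlation), including Ifit2 (log2 fold change 1.71, SE 0.13) and Oas1a (2.43, SE 0.31).

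Among markers of cell types, macrophage genes rose in 16 cases and fell in 3 of 21, or 16 and 4 adjusted over the list alone (median 1.52, camera adjusted p = 0.00015, adjusted p = 0.33 with an estimated correlation). Cx3cr1 rose from 1.42 ± 0.879 to 41.9 ± 17.8 CPM and Spp1 from 0.302 ± 0.147 to 6.78 ± 4.45 CPM, whereas Timd4, a marker of resident macrophages, fell from 3.47 ± 0.675 to 0.913 ± 0.499 CPM (SD, n = 5). Pericyte markers rose in 7 cases and fell in 1 of 8 (camera adjusted p = 0.037, adjusted p = 0.27 with an estimated correlation). That call was lost without sham replicate 3 (adjusted p = 0.053) or TAC replicate 4 (adjusted p = 0.054), within a range of 0.00014 to 0.27 over its alternatives. Fibroblast markers moved both ways, 6 up and 6 down of 16 (7 and 6 adjusted over the list alone, median 0.25, mean -0.13, camera adjusted p = 0.92). Under library size scaling 9 of them rose and 4 fell, with a median of 0.61. Pcolce rose by 1.55 (SE 0.09), and Scara5 and Dpep1 fell by 3.25 (SE 0.25) and 1.51 (SE 0.17). Endothelial markers rose in 5 cases and fell in 3 of 14 (median 0.03, mean -0.02, camera adjusted p = 0.92), with Egfl7 up by 0.62 (SE 0.08) and Aqp1 at a log2 fold change of -1.49 (SE 0.12). White adipocyte markers were lower, 7 down and 1 up of 8 (median -2.92, camera adjusted p = 0.020, adjusted p = 0.44 with an estimated correlation). Pck1 fell from 5.94 ± 3.13 to 0.159 ± 0.172 CPM and Retn from 2.11 ± 1.47 to 0.0551 ± 0.0552 CPM, while Fabp4, which endothelial cells also express, rose by 0.56 (SE 0.13) on the log2 scale. Without TAC replicate 4 the list median was -4.30 and Retn was at -5.83. The list call was lost when at least 1 CPM was required in at least 5 libraries (adjusted p = 0.061, within a range of 9.9e-05 to 0.44 over its alternatives). The ventricular marker Myl2 ranged from 0.881 to 218 CPM among sham libraries and averaged 4.80 ± 3.71 CPM in TAC, and its decrease was no longer called without sham replicate 5 (adjusted p = 0.064) or TAC replicate 2 (adjusted p = 0.053), within a range of 0.0023 to 0.16 over its alternatives. Its list was not called (2 up and 2 down of 5, camera adjusted p = 0.79). Erythroid markers rose in all 5 tested cases, without a list call (camera adjusted p = 0.18), and haemoglobin genes took 0.0191% ± 0.00680 of counts in sham and 0.0975% ± 0.102 in TAC (SD, n = 5, exact permutation p = 0.0079). Without TAC replicate 3, which held 0.278%, the difference between the group means went from 0.0784 to 0.0332 percentage points (exact permutation p = 0.016). Markers of smooth muscle, endocardium, lymphatic endothelium, neutrophils, T and NK cells, B and plasma cells, antigen-presenting cells, mast cells, nerve, mesothelium and skeletal muscle were not called as lists, with camera adjusted p from 0.098 to 0.92. Leaving out 1 library brought some of these lists past the threshold. Without sham replicate 4, antigen presentation markers (median 2.85, adjusted p = 0.00052, within a range of 0.00052 to 0.48 over the alternatives) and neutrophil markers (adjusted p = 0.036, range 0.0022 to 0.45) were higher. Without TAC replicate 1, antigen presentation (adjusted p = 0.039) and B and plasma cell markers (adjusted p = 0.04997, range 0.0076 to 0.52) were higher. Skeletal muscle markers were higher without TAC replicate 5 (adjusted p = 0.037) and in 5 other alternatives (range 2.3e-05 to 0.39), and nerve markers were lower with library size as the only scaling (adjusted p = 0.020, range 0.00086 to 0.41). Lists of brown fat, lung and thymus had too few tested members.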

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

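Apart from the counts over other splits, the comparison of endothelial with fibroblast markers, and the fit with library size scaling, which was fixed in advance, the tests of explanations here were chosen only after the results were seen. Of 100 distinct splits of the 10 libraries drawn from 126, 1 gave as many called genes, namely the real one with 8616, and the highest of the others gave 2. Every other split mixed libraries of the 2 groups, which widens the spread within its groups, so few calls were likely in advance. The real split ranked highest, but this count cannot exclude chance or tell surgery from another difference between the groups. After all libraries were thinned to the shallowest, 8038 genes were called, so depth was not the whole cause.

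Matrix and macrophage genes were higher in TAC, with Sparc, Col8a1 and Cx3cr1 among them. A larger share of all non-myocyte cells would raise endothelial and macrophage markers alike, but the endothelial median lay below that of macrophage markers by a log2 difference of -1.49 (permutation p = 0.0033) and below that of the matrix list by -2.66 (p = 2e-05, the smallest that 100000 permutations give). The comparison named in advance, endothelial minus fibroblast markers, gave -0.23 (permutation p = 0.80) and did not exclude it, because the fibroblast markers themselves moved both ways. More fibroblasts in their sham state would raise fibroblast markers and matrix genes together, but the 2 medians differed by -2.43 (permutation p = 2e-05). Permutation p-values for differences of list medians, here and below, come from shuffling genes between lists, not libraries, and treat genes as independent. The estimated correlation was 0.36 among endothelial, 0.32 among macrophage and 0.68 among matrix genes, so these p-values can be too small. A gain of macrophages, or a changed state of fibroblasts after constriction, may contribute and stays open, since these are bulk libraries.

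Immediate early genes such as Nr4a1 and Nr4a3, heat shock genes such as Hspa1a and clock genes such as Nr1d1 were lower in TAC. A few stressed sham libraries cannot be the whole cause, since the lowest sham library lay 1.02 above the highest TAC library in the mean log2 CPM of the immediate early and heat shock lists, against a difference in group means of 1.53. Sham replicates 2 and 5 stood highest (7.28 and 7.30), with the other sham libraries from 6.29 to 6.42. The heat shock list was chosen after the data were seen. In the immediate early list alone, fixed in advance, the lowest sham library was at 5.50 and the highest TAC library at 4.47. Stress during tissue collection could still differ between the groups. Over the 10 libraries with group means removed, the correlation of the 2 lists did not pass (Pearson's r = 0.70, permutation p = 0.070, Spearman's rho = 0.83, permutation p = 0.063, r = 0.78 without the 2 farthest libraries). Within groups, r was 0.73 in sham and -0.22 in TAC. A correlation within groups cannot show a difference between them, so this test cannot decide on stress at collection. Another time of day at collection could also contribute, but the clock genes do not decide on it. The test looked for a rise of clock genes peaking with Bmal1 and a fall of those peaking with Dbp. Their medians were -0.38 and -0.97, both below 0, and the difference of 0.59 did not pass (permutation p = 0.25). Handling and time of day are not in the labels and cannot be told apart from the surgery, whose own effect stays open too.

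Etv1 was lower in TAC by a log2 fold change of -0.68. A lower share of cardiomyocyte RNA through an equal gain of all other cells would raise their markers alike. Endothelial and macrophage markers moved apart instead, by -1.49 (permutation p = 0.0033), which argues only against such an equal gain. A gain of macrophages alone could also lower the share, so this test cannot decide on a lower share. Etv1 lay within the quartiles of the sarcomere list (-1.21 to -0.44), so a lower share of cardiomyocyte RNA or a general fall of myocyte transcripts stays open. A lower share was not tested for the energy metabolism, sarcomere, atrial identity, potassium channel and calcium handling lists, and stays open for them too. Scaling stays open as well, since with library size as the only scaling Etv1 was at -0.33 (adjusted p = 0.058, within a range of 1.2e-05 to 0.058 over its alternatives). A response of Etv1 transcription to pressure overload is a further candidate explanation that these libraries did not test.

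Single libraries stood far from the other 4 of their group in 29 of 290 groups of values. Chance would give about 14.5 if the values were independent and normally distributed. Related values count separately here, such as Hbb-bt, Hba-a2 and the haemoglobin share, so the excess over 14.5 cannot be taken at face value. Sham replicates 5 (7 cases) and 4 (6 cases) stood out most often. Highest and lowest refer to a library's own group. Sham replicate 5 was highest in the metabolic genes Ndufs1 (804 CPM), Idh3a (1064 CPM) and Mut (178 CPM), in Corin (715 CPM) and Dpep1 (223 CPM), and in the ventricular gene Myl2 (218 CPM, others at most 47.1). Sham replicate 4 was highest in the immune genes Cx3cr1 (2.96 CPM), Timd4 (4.64 CPM), Csf3r (2.01 CPM) and H2-Ab1 (93.2 CPM, others at most 19.9). It was lowest in Mmp9 (2.89 CPM). TAC replicate 3 was highest in the globin genes Hbb-bt (286 CPM) and Hba-a2 (148 CPM) and in the haemoglobin share (0.278%, others at most 0.0631%). TAC replicate 5 was highest in Vtn (7.07 CPM).

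TAC replicate 1 was highest in Sdha (747 CPM), Ndufs1 (372 CPM) and Idh3g (310.0 CPM). TAC replicate 2 was highest in Hspa1a (0.723 CPM), Ankrd2 (3.64 CPM), Timp1 (68.8 CPM) and Manf (67.8 CPM). Sham replicate 3 was highest in Scn4b (54.4 CPM) and lowest in Cry2 (61.0 CPM). Sham replicate 1 was highest in Mcm5 (8.07 CPM) and lowest in Synpo2 (208 CPM), and sham replicate 2 was lowest in Kcnd2 (44.6 CPM). Outside the gene counts, sham replicate 5 had the lowest share of reads ambiguous between genes (3.85%) and sham replicate 4 the highest share in no gene (3.80%). Ambiguous reads, which no comparison of genes uses, took 5.79% of all reads in TAC and 4.31% in sham, higher in 5 of 5 TAC libraries than in any sham library (exact permutation p = 0.0079).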

How the results depend on the processing

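Results without the 2 shallow sham libraries, with thinned libraries and with length and GC offsets were chosen only after the data were seen. With library size as the only scaling, 7741 genes were higher and 1929 lower, Etv1 was at -0.33, the rapid conduction median at -0.18 and Canx reversed to 0.14 (adjusted p = 0.18, within a range of 0.0034 to 0.18), because that scaling moves the median gene to 0.37. Requiring a log2 fold change of at least 1 left 1781 higher and 1229 lower genes by construction. Fixed lists higher and lower in TAC numbered 8 and 13 with camera, 13 higher with no filter on low counts, where more genes are tested, 14 higher with fry, and 0 higher and 1 lower with an estimated correlation (3 and 6 at an unadjusted p under 0.05). The rapid conduction list passed with fry alone (median -0.54, adjusted p = 0.0080, within a range of 0.0080 to 0.54), since fry does not compare it with other genes. Leaving out 1 library gave 4136 to 4602 higher and 3762 to 4224 lower genes, -0.74 to -0.61 for Etv1, -0.62 to -0.39 for the rapid conduction list, and 7 to 10 higher and 13 lower lists. Blocking by replicate number gave 4103 higher and 3917 lower genes. No label says that the numbers pair the samples, and libraries of one number showed little shared deviation from their group means (correlations from -0.036 to 0.080). Length and GC offsets gave 3616 higher and 5107 lower genes. Depth limits genes near the detection limit, such as Col11a1 with 12 sham counts.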

Other observations

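The 6 lists in this part, and their tests, were chosen only after the largest changes had been seen, so their p-values are not independent evidence. Enzymes of xenobiotic and amine metabolism were lower in TAC: of 18 tested, 15 fell and 0 rose over all genes and adjusted over the list alone (median log2 fold change -2.08, camera adjusted p = 2.5e-15, adjusted p = 0.026 with an estimated correlation). The carboxylesterase gene Ces1d fell from 350.0 ± 59.0 to 11.03 ± 6.998 CPM, the monoamine oxidase gene Maob from 179 ± 18.4 to 39.7 ± 2.101 CPM, and the glutathione transferase gene Gstm1 from 256 ± 28.2 to 59.9 ± 6.42 CPM (SD, n = 5). Heat shock genes fell in 14 of 15 cases (15 adjusted over the list alone) and rose in 0 (median -1.17, camera adjusted p = 3.2e-06, adjusted p = 0.23 with an estimated correlation), with Hspb1 at 545 ± 258 CPM in sham and 121 ± 7.33 in TAC. Cartilage and tendon matrix genes rose in 10 of 14 cases and fell in 1 (11 and 1 adjusted over the list alone, median 2.18, camera adjusted p = 0.00035, adjusted p = 0.23 with an estimated correlation). Angptl7 rose from 1.42 ± 0.479 to 72.7 ± 29.9 CPM, and the tendon factor gene Scx from 0.542 ± 0.218 to 4.19 ± 1.83 CPM (SD, n = 5). Clock genes peaking with Dbp fell in 8 of 10 cases (median -0.97, camera adjusted p = 0.00049, adjusted p = 0.23 with an estimated correlation), among them Hlf, from 121 ± 24.7 to 22.7 ± 9.14 CPM. The clock genes peaking with Bmal1 were not called (2 up and 1 down of 5, camera adjusted p = 0.99). Imprinted growth genes were not called either (3 up and 2 down of 13, camera adjusted p = 0.19), although Mest rose from 5.30 ± 1.56 to 67.3 ± 7.12 CPM (SD, n = 5), and Impact changed sign with library size as the only scaling. For the clock and imprinted lists the counts adjusted over the list alone were the same.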
